A study of Triticum aestivum with 4 samples.

How the data were processed

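RNA was extracted from roots of 45-day-old bread wheat (Triticum aestivum, genotype UAS-375) with a plant miniprep kit, and stranded, paired-end mRNA libraries were made with an Illumina TruSeq kit. Seeds of 1 group had been exposed to hypergravity (10 g for 12 h) before sowing, and seeds of the other group were untreated. Plants of both groups grew in a greenhouse in pipes under a completely randomized design. Each group had 2 libraries. The labels do not say whether the libraries of a group came from separate plants or pools of plants, so the p-values measure the spread between these libraries and nothing wider. The submitters' processing notes name RSEM, a program that estimates transcript abundance, without a version. The assembler, the aligner and any filter are not given in the sources used here. The identifiers are in the style of a Trinity de novo assembly, and no genome positions were used.

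The deposited table held 147297 transcripts with their length, a best protein hit with its species where 1 was found, and 1 value per group, called FPKM per the file headers. The deposited values carried 2 kinds of unit in the same columns, so each column was treated as a signal whose meaning depended on the row. In 91482 rows the deposited signal was the sum, over the 2 libraries of a group, of read counts each divided by a size factor. These sums had long decimals, and every one (100%) could be split into exactly 1 pair of whole counts. The largest error of the best pair was 5.81e-10, the smallest error of a second-best pair was 4.67e-07 and the tolerance was 1e-09. The size factors were 1.01 and 1.06 in control and 0.959 and 0.971 in hypergravity, and they equalled the median-of-ratios factors recomputed from the recovered counts. The libraries are called a and b here, because nothing paired a recovered library with a replicate number. In the other 55815 rows the deposited values had at most 2 decimals, were taken as FPKM per the file headers, and were described but not tested, since they give 1 value per group. How the 2 libraries were combined in these rows, as a sum or a mean, is not given in the sources used here.

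Recovered counts summed to 49424285 in control a, 53346750 in control b, 46604327 in hypergravity a and 47850533 in hypergravity b. The lowest recovered count was 9 in each library, so the 91482 rows hold no transcript at 0. Isoforms and the 3 wheat subgenomes share many reads, so a change of 1 transcript can include a shift of reads between near copies, and counting error is only part of the spread. The median standard error of a log2 fold change was 0.18.

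Hypergravity was compared with control by limma 3.58.1 in R 4.3.3, as log2 of the recovered count divided by its size factor plus a pseudocount of 1, with eBayes and a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over the 91482 transcripts, and a transcript was called higher or lower at an adjusted p under 0.05. A filter on a mean of at least 1 removed no transcript. The test had 2 residual degrees of freedom and a prior of 7.91. In simulated data with 2 libraries per group, the same test recovered 8 of 67 transcripts changed 1.5-fold, 33 of 67 changed 2-fold and 57 of 66 changed 4-fold, and it called 8 unchanged transcripts. Only 200 of 91482 simulated transcripts were changed, far fewer than were called in the data. An adjusted p under 0.05 was therefore harder to reach there, and these shares do not give the recovery in the data. A list of 100 simulated transcripts raised 1.5-fold was called by the list test, and 0 of 20 random lists were. The simulated transcripts varied independently, whereas members of some real lists varied together. The estimated correlation was largest for aquaporins (0.60) and lower in other lists, such as 0.006 for calcium signalling and 0.02 for cytoskeleton. The random lists therefore cannot show how often a list of correlated members is called falsely.

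The 34 gene lists were fixed, as text patterns searched in the protein hit descriptions, before the data were examined, as were the test, its thresholds and the rule for named transcripts. List members are transcripts, so isoforms of 1 assembled gene count separately. Lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, so a high adjusted p does not by itself show correlated members. Named transcripts were the 12 with the largest positive and the 12 with the largest negative log2 fold change among called transcripts whose groups did not overlap, 1 per gene, and at most 4 called members of each described list. After the data were seen, transcripts were also sorted by the species of the best hit. Pooid grasses, the subfamily of wheat, barley, Brachypodium and Aegilops tauschii (called goatgrass here), were separated from panicoid grasses (Setaria, Panicum, sorghum and maize), from rice and other grasses, and from all other species. The list tests and the rule for named transcripts were then repeated among pooid hits, and 6 further lists were added and also tested without the assembled genes of the top named transcripts. A best hit gives the closest protein in the authors' search and does not prove the species of the RNA. A table of wheat reference genes matched 11 of 108876 protein accessions and was not used for names.

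The other settings were pseudocounts of 0.1 and 0.5, no filter, means of at least 5 and, added later, 50, quantile normalization, eBayes without trend, leaving out each library, a log2 fold change of at least 1, sums per assembled gene and 1 transcript per gene in the list test. Scaling to the recovered total, voom weights, pooid hits alone with their own size factors and removal of each library's trend with transcript length (a spline with 5 degrees of freedom) were also added after the data were seen. The fixed plan expected 1 value per library in the table, and the same test was applied to the recovered values. DESeq2, foreseen as a second test, was not run, the recovered counts were tested on the log scale, and a replicate block was not run, since the recovered libraries have no replicate number. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.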

Results

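The series measured mRNA of wheat roots 45 days after seeds had been held at 10 g for 12 h, against roots from untreated seeds, with 2 libraries per group. Its title concerns stronger root growth after hypergravity, and the comparison asks which transcripts differ in such roots. Of 147297 assembled transcripts, 91482 in 47167 assembled genes had values per library, with totals of 49424285 and 53346750 counts in control and 46604327 and 47850533 in hypergravity. Pearson's r across transcripts was 0.989 between the control libraries and 0.987 between the hypergravity libraries. It lay between 0.942 and 0.956 across groups. The first principal component separated the groups and held 78.6% of the variance. The 10 leading transcripts took 1.76% and 1.88% of the counts in control and 1.41% and 1.39% in hypergravity. Levels are given as mean normalized counts ± SD with n = 2 libraries per group, changes as log2 fold change ± SE of hypergravity against control, and adjusted p as Benjamini-Hochberg values from limma.

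Transcripts of cystathionine gamma-synthase 1 and of a sterol demethylase were among those that rose most in roots from hypergravity seeds, and a flowering-promoting factor 1-like and a lipid-transfer protein transcript were among those that fell most. Among transcripts with a pooid best hit, a cystathionine gamma-synthase 1 transcript of goatgrass best hit (TRINITY_DN1078_c0_g1_i11), which codes for the enzyme committing carbon to methionine synthesis, stood at 142 ± 4.88 in control and 1814 ± 41.7 in hypergravity. Its log2 fold change was 3.66 ± 0.11 with an adjusted p of 1.62e-07. A transcript of obtusifoliol 14-alpha demethylase (TRINITY_DN1703_c0_g1_i1, goatgrass), an enzyme of plant sterol synthesis, went from 90.6 ± 7.18 to 925 ± 55.5, a change of 3.34 ± 0.13. A FAR1-RELATED SEQUENCE 5-like transcript (TRINITY_DN172_c0_g1_i3, goatgrass), of a family of transposase-derived transcription factors, rose from 71.6 ± 3.67 to 1235 ± 40.2. In the other direction, flowering-promoting factor 1-like protein 2 (TRINITY_DN26570_c0_g1_i1, goatgrass) fell from 324 ± 9.05 to 21.7 ± 2.74, a change of -3.84 ± 0.20 with an adjusted p of 2.30e-06.

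By limma, 12378 transcripts (13.5%) in 7499 assembled genes were higher and 10928 (11.9%) in 6773 assembled genes were lower in hypergravity at an adjusted p under 0.05. The unadjusted p was under 0.05 for 34190 transcripts. At least 2-fold changes were called for 4515 higher and 2894 lower transcripts. Both hypergravity libraries lay on 1 side of both control libraries in 63.9% of transcripts, where chance gives 33.3% for a single transcript. All transcripts share the same libraries, so the gap between these shares does not measure evidence against chance. At least 2-fold apart, 4535 higher and 2915 lower transcripts were separated in this way. Summed per assembled gene, 6726 of 47167 genes were higher and 5799 were lower. The lower count fell to 6983 without control b and to 7145 without hypergravity b, so its size rests on which libraries are used.

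Of the 12 transcripts that rose most, 6 had pooid, 2 panicoid and 4 other best hits. The largest change, 5.96 ± 0.17 with an adjusted p of 1.62e-07, was of sucrose synthase 2 (TRINITY_DN89952_c0_g1_i1), which cleaves sucrose for growing tissue, from 35.9 ± 8.98 to 2269 ± 216. Its best hit was in Setaria italica, a panicoid grass, and a further sucrose synthase 2 row of the same species had an FPKM of 0 in control and 210.56 in hypergravity as the authors' values. A methionine adenosyltransferase transcript with a maize hit (TRINITY_DN9287_c0_g1_i1), for the enzyme that makes S-adenosylmethionine, rose by 3.65 ± 0.10 to 3629 ± 227. Goatgrass hits of exocyst subunit EXO70B1-like (TRINITY_DN5088_c1_g2_i3), which tethers secretory vesicles, rose by 3.86 ± 0.18, of the immune receptor RPM1-like (TRINITY_DN5404_c0_g1_i3) by 3.56 ± 0.14 and of a further cystathionine gamma-synthase 1 (TRINITY_DN18538_c0_g1_i7) by 3.34 ± 0.19. The amino acid transporter AVT1I-like (TRINITY_DN22828_c1_g1_i3, spinach hit) rose by 3.78 ± 0.19. A class I small heat shock protein (TRINITY_DN1684_c0_g2_i2, Selaginella hit) rose by 3.78 ± 0.14, an ADP,ATP carrier (TRINITY_DN1389_c2_g1_i1, silver malletwood hit) by 3.42 ± 0.14 and a respiratory supercomplex factor 2 homolog (TRINITY_DN45796_c0_g1_i2, cork oak hit) by 3.39 ± 0.20.

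Of the 12 transcripts that fell most, 3 had pooid best hits, 7 had hits in other seed plants and 2 in algae. Whether the transcripts with hits outside the grasses came from wheat was not tested. A tubulin alpha-1 transcript with a morning glory hit (TRINITY_DN5498_c0_g1_i9), a subunit of microtubules, went from 1808 ± 206 to 71.9 ± 14.7, a change of -4.64 ± 0.16. Actins with hits in tobacco, walnut and Syzygium changed by -4.33 ± 0.21, -3.30 ± 0.16 and -3.29 ± 0.41. A pair of polyubiquitin 11 transcripts (Camelina and tobacco hits) changed by -4.27 ± 0.18 and -3.95 ± 0.29, and tubulin alpha-3 (olive hit) by -3.12 ± 0.22. A translation elongation factor-like protein (Bathycoccus hit) changed by -3.93 ± 0.18 and a beta tubulin (Ostreococcus hit) by -3.68 ± 0.12. Among goatgrass hits, non-specific lipid-transfer protein 4.3 (TRINITY_DN6076_c2_g1_i2) fell from 255 ± 51.8 to 20.7 ± 2.75 and PIN-LIKES 7-like (TRINITY_DN15358_c0_g1_i3), of a family that holds auxin in the endoplasmic reticulum, from 799 ± 87.6 to 98.9 ± 7.18.

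The same rule among pooid hits, applied after the data were seen, added a further obtusifoliol 14-alpha demethylase-like transcript (TRINITY_DN473_c0_g2_i1, 3.27 ± 0.11), receptor like protein 42 (3.04 ± 0.14), peroxidase 2-like (3.00 ± 0.16), O-fucosyltransferase 34 (2.99 ± 0.22), vacuolar amino acid transporter 1-like (2.97 ± 0.21) and the putative resistance protein RGA1 (2.97 ± 0.14) among the higher. Among the lower it added a GDSL esterase/lipase (-2.85 ± 0.20), the subtilisin-like protease SBT3.9 (-2.81 ± 0.19) and bHLH47-like (-2.76 ± 0.20), of a family of transcription factors. It also added the ubiquitin ligase SINA-like 10 (-2.71 ± 0.21), homeotic protein female sterile-like (-2.68 ± 0.28), heat stress transcription factor B-2b-like (-2.49 ± 0.21) and a mitochondrial small heat shock protein (-2.49 ± 0.34). A flavonoid O-methyltransferase-like transcript (-2.42 ± 0.28) and putative ripening-related protein 4 (-2.34 ± 0.19) completed the group.

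**Figure D1:**
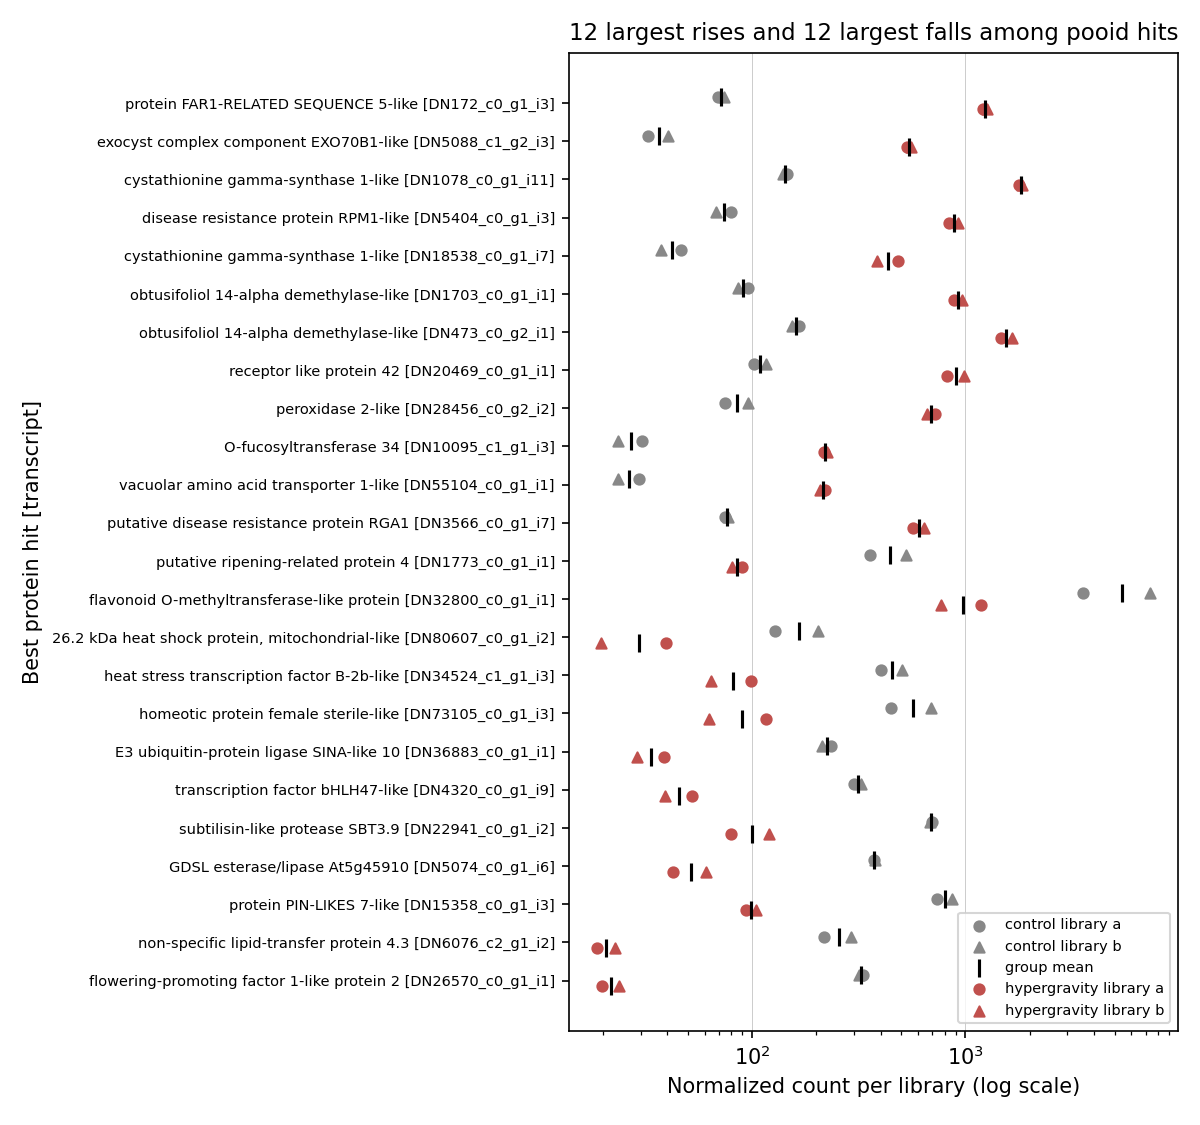
Normalized counts (log axis) of the 12 transcripts that rose most and the 12 that fell most among pooid hits, with 1 point per library of control (grey) and hypergravity (red) and a line at each group mean. In every transcript shown, both hypergravity libraries lie on 1 side of both control libraries.

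Cellulose synthases and related enzymes, which build wall glucans, were higher as a group: 36 of 95 rose, 6 fell and 53 were not called, or 39 and 6 adjusted over the list alone. The list was called higher (camera of limma, adjusted p = 1.90e-05; adjusted p = 0.873 with an estimated correlation). A cellulose synthase A catalytic subunit 1 transcript (goatgrass hit) went from 25.9 ± 3.19 to 164 ± 6.59, and a catalytic subunit 8 transcript (Panicum hallii hit) from 329 ± 8.55 to 1289 ± 109. Among pooid hits 26 of 70 rose and 6 fell (adjusted p = 0.000149; adjusted p = 0.813 with an estimated correlation). Of 19 expansins, which loosen walls, 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.724). Expansin-B6-like (goatgrass) changed by 1.81 ± 0.21 and expansin-A10 by -0.62 ± 0.11. Of 42 xyloglucan enzymes 9 rose and 10 fell, or 9 and 11 adjusted over the list alone (adjusted p = 0.983). Of 108 pectin-modifying proteins 26 rose and 8 fell, or 28 and 8 adjusted over the list alone (adjusted p = 0.116), with polygalacturonase 1 beta-like protein 3 at 1.28 ± 0.10. Of 296 phenylpropanoid and lignin transcripts 71 rose and 33 fell, or 77 and 38 adjusted over the list alone (adjusted p = 0.239), among them a phenylalanine ammonia-lyase (1.55 ± 0.09) and dirigent protein 22-like (-1.75 ± 0.27). The phenylpropanoid median was -0.02, against a mean of 0.09 and an upward test.

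Calcium signalling proteins were higher: 119 of 411 rose, 29 fell and 263 were not called, or 128 and 35 adjusted over the list alone (camera of limma, adjusted p = 2.75e-05; adjusted p = 0.621 with an estimated correlation). Examples are calcium-dependent protein kinase 20 (Brachypodium hit), from 142 ± 19.2 to 706 ± 4.68, and calmodulin-binding protein 60 D-like (goatgrass), from 302 ± 15.5 to 1485 ± 10.3. Of 187 WRKY factors, which regulate defence genes, 56 rose and 15 fell, or 63 and 17 adjusted over the list alone (adjusted p = 0.00105; adjusted p = 0.873 with an estimated correlation). WRKY 59 (goatgrass) changed by 2.79 ± 0.22. The median of pooid WRKY factors was 0.15 between the groups, and it also differed by 0.25 between the control libraries and by 0.29 between the hypergravity libraries. The WRKY call was lost without control a (adjusted p = 0.0509) and without hypergravity a (0.0751). Among pooid hits 91 of 329 calcium transcripts rose and 25 fell (adjusted p = 3.96e-05; adjusted p = 0.813 with an estimated correlation), and 54 of 184 WRKY transcripts rose and 15 fell (adjusted p = 0.00041; adjusted p = 0.894 with an estimated correlation). The defence list was not called, with 65 of 343 higher and 57 lower, or 70 and 63 adjusted over the list alone (adjusted p = 0.787). Its pattern for thionins also took 137 methionine or cystathionine enzymes, and of the other 206 members 43 rose and 43 fell. An endochitinase 1-like transcript (goatgrass), whose product degrades chitin, changed by 2.89 ± 0.13. Without control b the defence list was called higher (adjusted p = 0.0208).

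Sugar metabolism and transport was higher, with 54 of 196 members up and 23 down, or 59 and 26 adjusted over the list alone (camera of limma, adjusted p = 0.0155; adjusted p = 0.873 with an estimated correlation). Trehalose-phosphate phosphatase 1 (goatgrass), which forms trehalose, went from 311 ± 14.5 to 1143 ± 84.3, and sucrose:sucrose 1-fructosyltransferase-like, of fructan synthesis, from 184 ± 13.4 to 514 ± 10.5. The sugar call was lost without hypergravity a (adjusted p = 0.0624). Cytoskeleton transcripts were called higher, with 152 of 703 up and 59 down, or 157 and 60 adjusted over the list alone (adjusted p = 0.0359; adjusted p = 0.873 with an estimated correlation). The kinesins KIN-6 and KIN-7H (goatgrass), motors on microtubules, changed by 1.51 ± 0.19 and 1.35 ± 0.18. In the other direction, tubulin and actin transcripts with hits outside the grasses were among those that fell most. Examples are tubulin alpha-1 with a morning glory hit (-4.64 ± 0.16) and an actin with a tobacco hit (-4.33 ± 0.21). These falls may not be of wheat transcripts, and the species of the RNA was not tested. The cytoskeleton call was lost without control a (adjusted p = 0.168), control b (0.19) or hypergravity b (0.0986) and at a mean of at least 50 (0.0578). Among pooid hits 52 of 179 sugar transcripts rose and 23 fell (adjusted p = 0.00848), and 81 of 432 cytoskeleton transcripts rose and 27 fell (adjusted p = 0.0216), both with adjusted p = 0.813 with an estimated correlation. The pooid cytoskeleton call was lost with the length trend removed (adjusted p = 0.0511), and its members were long, with a median of 1631.5 bases. Of 236 cell cycle and DNA replication transcripts 42 rose and 25 fell, or 43 and 26 adjusted over the list alone (adjusted p = 0.297), with cyclin-B1-1-like going from 37.0 ± 4.86 to 151 ± 11.1.

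Aquaporins, the water channels of root membranes, were lower: 27 of 70 fell and 9 rose, or 36 and 10 adjusted over the list alone (camera of limma, adjusted p = 0.000193; adjusted p = 0.873 with an estimated correlation). TIP1-1 (TRINITY_DN16795_c0_g1_i1, goatgrass) went from 411 ± 114 to 161 ± 30.7 and PIP2-6 from 1226 ± 338 to 498 ± 158. The median of pooid aquaporins was -0.46 between the groups, and it also differed by 0.33 between the control libraries and by 0.31 between the hypergravity libraries. Of 152 iron and zinc transcripts 63 fell and 17 rose, or 70 and 22 adjusted over the list alone (adjusted p = 0.000193; adjusted p = 0.873 with an estimated correlation). Nicotianamine synthase 1 (goatgrass), which makes a metal chelator, changed by -1.70 ± 0.25 and zinc transporter 5-like by -1.58 ± 0.30. Of 149 phosphate transcripts 46 fell and 27 rose, or 57 and 29 adjusted over the list alone (adjusted p = 0.00326; adjusted p = 0.873 with an estimated correlation), with phosphate transporter 1-13 at -1.98 ± 0.18. Among pooid hits 24 of 59 aquaporins fell and 4 rose (adjusted p = 1.45e-05; adjusted p = 0.894 with an estimated correlation), 57 of 134 iron and zinc transcripts fell and 13 rose (adjusted p = 8.82e-05; adjusted p = 0.813 with an estimated correlation) and 46 of 135 phosphate transcripts fell and 20 rose (adjusted p = 0.000211; adjusted p = 0.813 with an estimated correlation). Of the 14 phosphate transcripts with other hits 7 rose and 0 fell, with a median of 0.76. Over all hits the phosphate transcripts that fell lay in 19 of 67 assembled genes and those that rose in 15. Nitrogen transport and assimilation was not called, with 55 of 301 higher and 71 lower, or 64 and 79 adjusted over the list alone (adjusted p = 0.297), although high-affinity nitrate transporter 2.1-like (goatgrass) rose from 93.3 ± 0.47 to 430 ± 17.4.

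Heat shock proteins and their regulators were called lower as a list: 195 of 586 fell and 122 rose, or 211 and 134 adjusted over the list alone (camera of limma, adjusted p = 0.0444; adjusted p = 0.873 with an estimated correlation). Heat stress transcription factor A-2a-like (goatgrass) went from 821 ± 262 to 203 ± 56.0. The call over all hits was lost without control b (adjusted p = 0.109) and under quantile normalization (0.0589). Among pooid hits 132 of 330 fell and 38 rose (adjusted p = 9.43e-06; adjusted p = 0.813 with an estimated correlation), and these took 2.08% and 2.39% of the counts in control and 1.65% and 1.52% in hypergravity. Of the 256 members with other hits 84 rose and 63 fell, with a median of 0.13, and the difference from pooid hits was not tested. Of 234 glutathione transferases, which conjugate toxic compounds, 52 fell and 19 rose, or 59 and 19 adjusted over the list alone (adjusted p = 0.00326; adjusted p = 0.873 with an estimated correlation). The glutathione transferase call was lost without control b (adjusted p = 0.0665) or hypergravity b (0.132). Peroxidases (60 of 239 higher and 65 lower, or 77 and 71 adjusted over the list alone; adjusted p = 0.73) and other antioxidant proteins (27 of 166 higher and 21 lower, or 29 and 21 adjusted over the list alone; adjusted p = 0.598) were not called.

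Histones and ribosomal proteins had calls of opposite direction in different classes of best hit, whose difference was not tested. Of 86 histones 33 fell and 17 rose, or 35 and 17 adjusted over the list alone (camera of limma, adjusted p = 0.0444; adjusted p = 0.873 with an estimated correlation), while fry pointed upward (adjusted p = 0.941). Among pooid hits 19 of 30 fell and 0 rose (adjusted p = 3.34e-06; adjusted p = 0.813 with an estimated correlation), such as a histone H2A-like transcript, from 990 ± 319 to 310 ± 82.6, whereas 13 of 20 cork oak hits rose and 1 fell. Of 21 histones with hits in other seed plants 9 fell and 3 rose, with a median of -0.50. The pooid histone median differed by 0.37 between the control libraries and by 0.50 between the hypergravity libraries. The call over all histones was lost without hypergravity b (adjusted p = 0.102), under quantile normalization (0.0582) and with the length trend removed (0.114). Of 1168 ribosomal protein transcripts 301 rose and 173 fell, or 327 and 198 adjusted over the list alone (adjusted p = 0.0295, called higher; adjusted p = 0.621 with an estimated correlation). Among pooid hits the direction was reversed: 105 of 319 fell and 3 rose, or 114 and 4 adjusted over the list alone (adjusted p = 4.12e-08; adjusted p = 0.813 with an estimated correlation). Ribosomal protein L35a-1 with a Brachypodium hit went from 1823 ± 299 to 905 ± 98.9, and S4-3-like with a moss hit from 73.9 ± 8.35 to 639 ± 19.6. Their median change was -0.27 among pooid hits, 0.48 among 126 cork oak hits and 0.55 among 162 algal, moss and lycophyte hits. The upward call was lost without hypergravity a (adjusted p = 0.109) and at a mean of at least 50 (0.123).

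**Figure D2:**
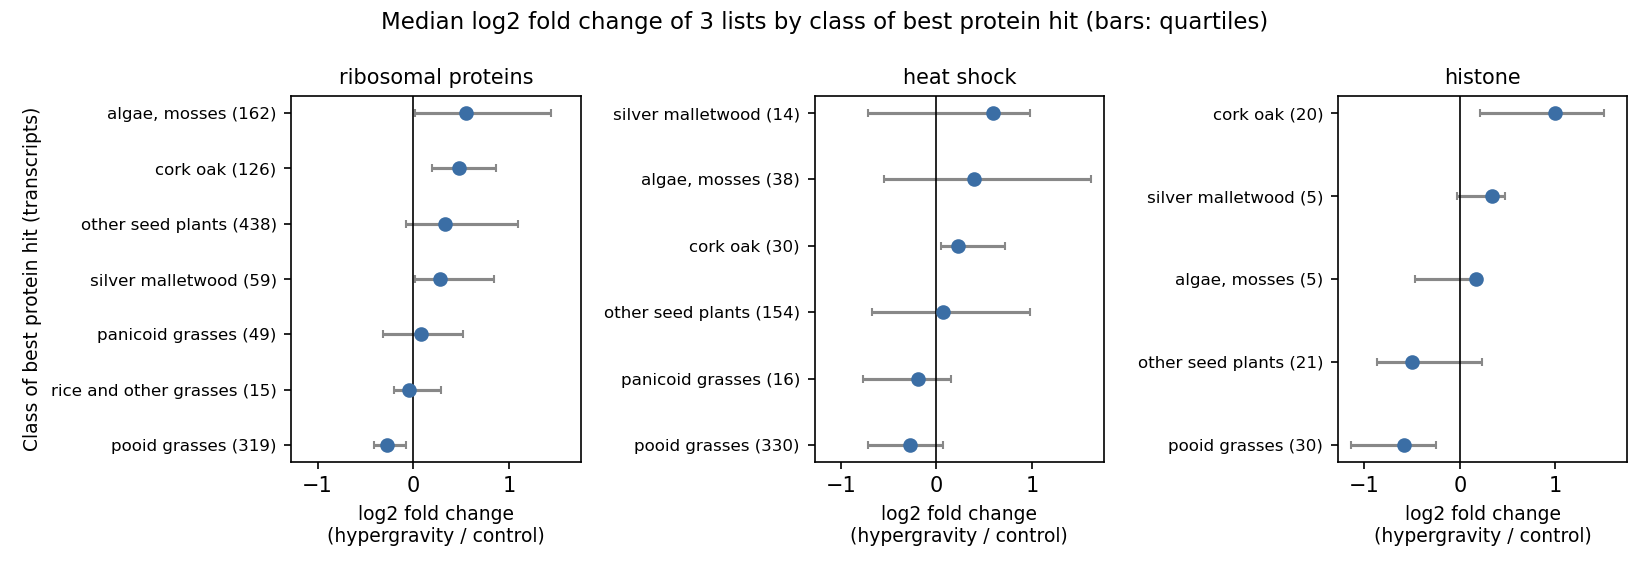
Median log2 fold change, with the 25th to 75th percentile as error bars, of ribosomal protein, heat shock and histone transcripts by class of best protein hit, for classes of at least 5 members. The ribosomal protein median is -0.27 among pooid hits and 0.55 among algal, moss and lycophyte hits.

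Hormone lists moved in several directions. Jasmonate transcripts were called higher (40 of 140 up and 18 down, or 43 and 19 adjusted over the list alone; camera of limma, adjusted p = 0.037; adjusted p = 0.873 with an estimated correlation), with TIFY 9-like (goatgrass), of the family that represses jasmonate responses, at 2.32 ± 0.24. Gibberellin transcripts were called higher (15 of 46 up and 8 down, or 17 and 8 adjusted over the list alone; adjusted p = 0.0295; adjusted p = 0.873 with an estimated correlation). Among them, the chitin-inducible gibberellin-responsive protein 1 went from 2933 ± 18.1 to 6917 ± 694, and the growth repressor DELLA protein RHT-1 from 299 ± 98.6 to 144 ± 50.4. A further DELLA transcript, SLN1 (Brachypodium hit), went the other way, from 51.8 ± 7.75 to 107 ± 15.6. Ent-copalyl diphosphate synthase 1 (goatgrass) changed by -1.30 ± 0.20. The gibberellin transcripts that rose lay in 8 of 25 assembled genes and those that fell in 6. Without control a neither the gibberellin list (adjusted p = 0.391) nor the jasmonate list (0.22) was called, nor without hypergravity a (0.116 and 0.215). Of 9 brassinosteroid transcripts 2 fell and 0 rose, or 2 and 0 adjusted over the list alone (adjusted p = 0.0295; adjusted p = 0.873 with an estimated correlation). These were isoforms of the receptor kinase BRL2 at -0.95 ± 0.09 and -0.92 ± 0.09, and the call was lost without control b (adjusted p = 0.0622), at a mean of at least 50 (0.0533) and among pooid hits (0.128). Auxin (24 of 251 up and 45 down, or 24 and 45 adjusted over the list alone; adjusted p = 0.166), cytokinin (18 of 140 up and 14 down, or 18 and 14 adjusted over the list alone; adjusted p = 0.628) and ethylene (51 of 280 up and 59 down, or 56 and 62 adjusted over the list alone; adjusted p = 0.598) were not called. Single members included the auxin synthesis enzyme YUCCA9 (-1.21 ± 0.31), cytokinin dehydrogenase 5 (1.75 ± 0.19), which degrades cytokinin, and ERF109-like (2.65 ± 0.27). Abscisic acid transcripts (19 of 45 up and 11 down, or 21 and 11 adjusted over the list alone) were not called (adjusted p = 0.116), but were without control b (0.0141) and without hypergravity b (0.0228). The phenylpropanoid list was also called higher without control b (adjusted p = 0.00347) and without hypergravity b (0.00672).

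Root development regulators were called lower by a narrow margin, with 25 of 116 down and 17 up, or 32 and 18 adjusted over the list alone (camera of limma, adjusted p = 0.049; adjusted p = 0.873 with an estimated correlation). Scarecrow-like protein 9 (goatgrass), of the GRAS family of transcription factors, changed by -1.46 ± 0.35 and LOB domain-containing protein 4-like by -1.38 ± 0.24. The root development call was lost without control b (adjusted p = 0.367) or hypergravity b (0.144), among pooid hits (0.0784), at a mean of at least 50 (0.126), under quantile normalization (0.0582) and with the length trend removed (0.0689). MYB (28 of 215 up and 49 down, or 32 and 51 adjusted over the list alone; adjusted p = 0.249) and NAC factors (20 of 124 up and 21 down, or 23 and 26 adjusted over the list alone; adjusted p = 0.249) were not called, with MYB30-like at 2.02 ± 0.18 and NAM-A1 at -1.70 ± 0.20. Among the 17 photosynthesis markers of shoot tissue 3 rose and 5 fell, or 3 and 6 adjusted over the list alone (adjusted p = 0.724), and they took at most 0.0064% of the counts in any library. Markers of other organisms (4 of 56 up and 11 down, or 8 and 15 adjusted over the list alone; adjusted p = 0.151) and transposable elements (0 of 6 up and 1 down, or 0 and 1 adjusted over the list alone; adjusted p = 0.576) were not called. Of the 43 other-organism markers with a pooid hit 31 were tobamovirus multiplication proteins, which are host proteins, and 11 of the 43 fell (adjusted p = 0.00203; adjusted p = 0.813 with an estimated correlation). Of the 13 with other hits, 10 of them in cork oak, 4 rose and 0 fell, with a median of 0.46. The median and mean of 2 more lists differed in sign: ethylene, with a median of -0.03, a mean of 0.01 and a downward test, and expansins, with -0.06, 0.19 and an upward test.

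**Figure D3:**
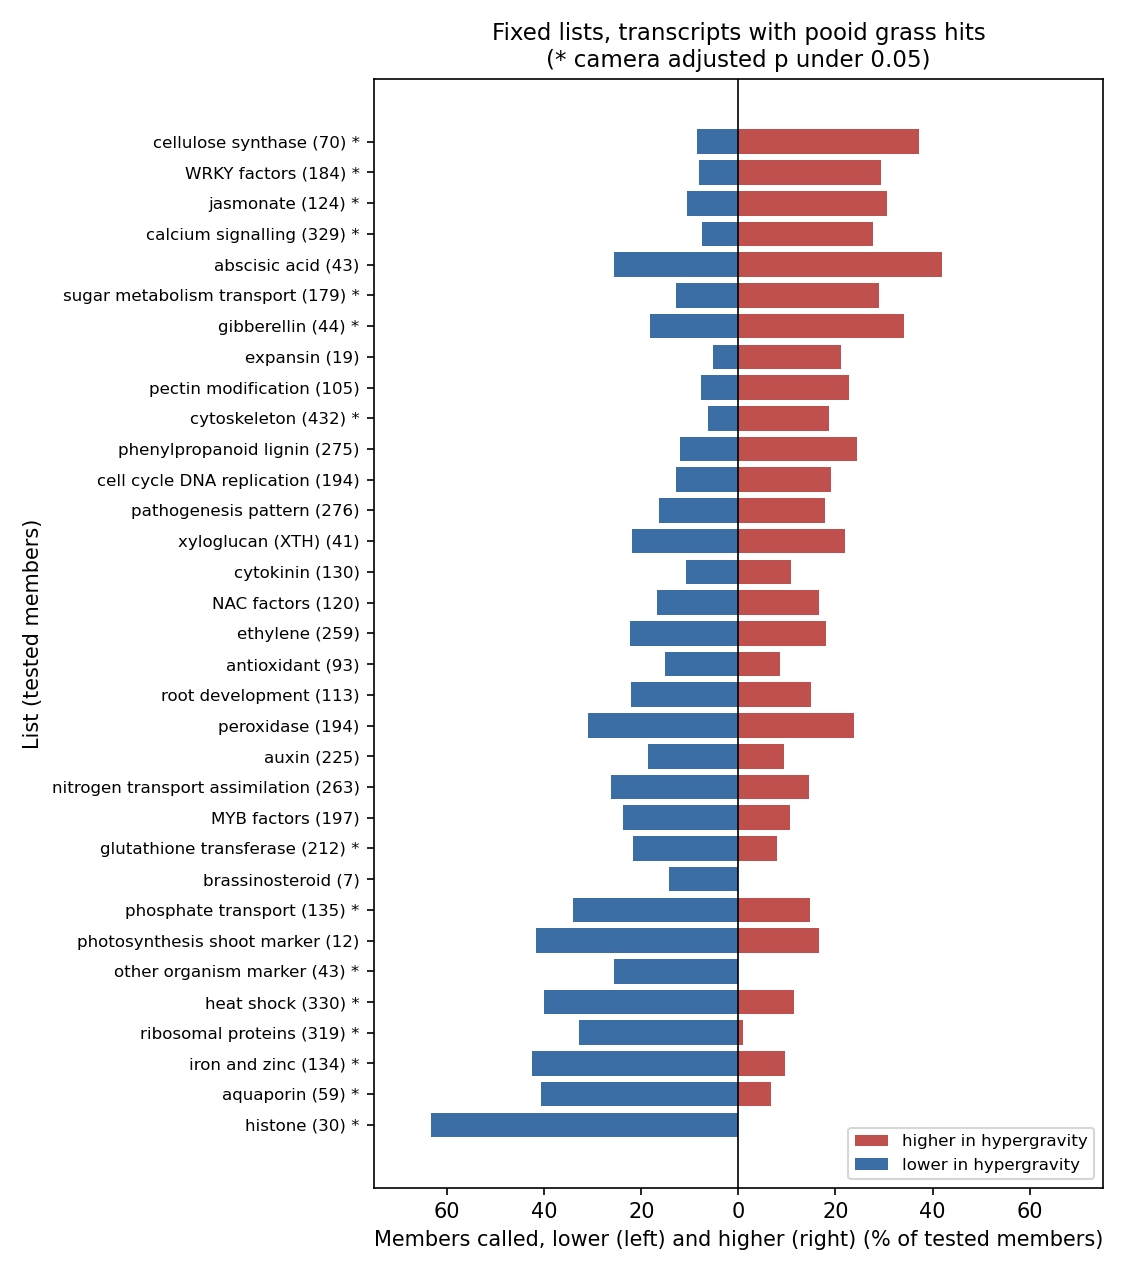
Percentage of the members of each fixed list, among pooid hits, that were called higher or lower in hypergravity. Ribosomal proteins, with 105 of 319 lower, and calcium signalling, with 91 of 329 higher, are among the lists marked with an asterisk (camera adjusted p under 0.05).

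Calls are given by class of best hit as counts, with no test of the difference between classes. Pooid hits had nearly equal calls, 7825 higher and 7741 lower of 59391. Cork oak hits were called higher in 26.4% and lower in 2.55% of 1957, and algal, moss and lycophyte hits in 27.2% and 6.08% of 1613. Cork oak hits took 0.363% and 0.344% of the counts in control and 0.475% and 0.53% in hypergravity. Pooid transcripts of at most 800 bases were higher in 7.92% and lower in 15.6%, and those over 2000 bases were higher in 19.0% and lower in 9.32%. Across pooid transcripts, length had a Spearman's rho of 0.19 with the group change, but of -0.24 with the difference of control b from a and -0.42 with that of hypergravity a from b, so the libraries of 1 group also differed with length. With the length trend removed, the medians among pooid hits were -0.19 for ribosomal proteins, -0.53 for histones, -0.41 for aquaporins and -0.28 for heat shock proteins.

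The 55815 rows with 1 FPKM value per group, the authors' values with no replicate, were described without a test. Whether such a value is a sum or a mean over the 2 libraries is not given in the sources used here. They summed to 53222.96 in control and 155614.69 in hypergravity. Panicoid hits made most of the difference: 13333 rows summed to 4975.03 and 77361.46, and 11244 of them (84.3%) were at 0 in control only, against 25 at 0 in hypergravity only. These rows covered many functions, such as a metallothionein-like protein 2C of Setaria italica (0 and 201.19), a 60S ribosomal protein L36-3-like of Panicum hallii (0 and 155.86) and a phenylalanine/tyrosine ammonia-lyase of maize (0 and 142.68). Pooid hits, at 10105 rows, had sums in a ratio of 1.32, with 11.1% at 0 in control only. Among the 2548 panicoid hits with values per library 491 were higher and 274 lower, with a median of 0.06, and 30 were at least 4-fold higher and 1 at least 4-fold lower. They took 2.66% and 2.69% of the counts in control and 2.79% and 2.72% in hypergravity.

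**Figure D4:**
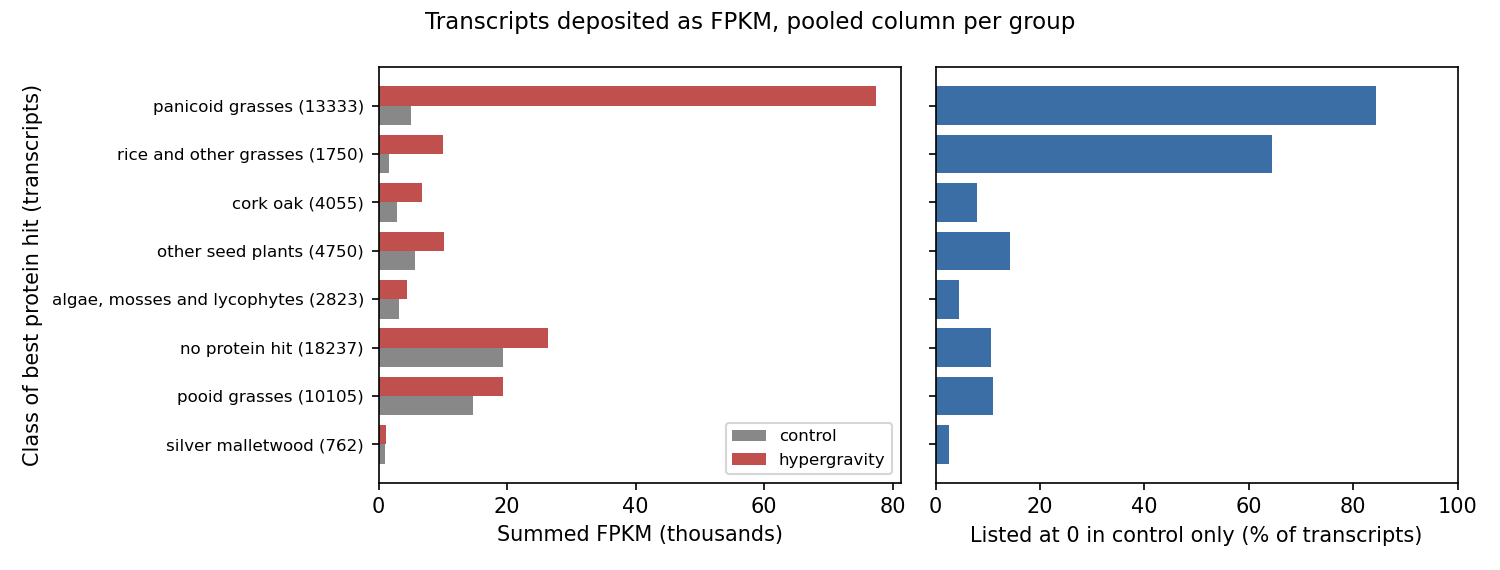
Summed FPKM of the rows with 1 value per group, in control and hypergravity, and the percentage of rows at 0 in control only, by class of best protein hit. Panicoid hits sum to 4975.03 in control and 77361.46 in hypergravity, and 84.3% of them are at 0 in control only.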

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

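All tests in this part were chosen only after the results were seen. The rows with 1 FPKM value per group lay outside the tested data, and the summed FPKM of 3 classes of best hit stood well above control there. The ratio of hypergravity to control was 15.55 for panicoid grasses, 6.066 for rice and other grasses and 2.399 for cork oak, against 1.32 for pooid grasses. These ratios come from 1 pooled value per group and were not tested against replicates.

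The first pattern is the near absence of panicoid hits from control. Deeper coverage of low transcripts in hypergravity would leave values at 0 in control mainly among low rows. Of 1563 panicoid rows with at least 10 FPKM in hypergravity 71.3% were at 0 in control, against 34.1% of 223 such pooid rows. Counted rows held at least 9 counts in every library, so rows high in hypergravity may be in this set because control was low. A large share at 0 was then partly built in, also for pooid rows (11.1% over all pooid FPKM rows). The shares therefore do not decide on deeper coverage. Wheat genes switched on by the treatment would have mostly pooid hits if they resembled the counted rows with a hit, of which 83.3% were pooid. Of the FPKM rows with a hit at 0 in control only, 76.8% were panicoid, against 3.09% of those at 0 in hypergravity only. The FPKM rows had another make-up, with 18.1% of all of them pooid and 23.9% panicoid, so 83.3% is not a matched baseline. RNA of another grass related to Setaria, Panicum, sorghum or maize in the hypergravity libraries is a candidate explanation: over the 34 fixed lists, the panicoid rows at 0 in control only followed the counted pooid rows (Spearman's rho 0.947 across lists), as a whole transcriptome would, though any broad sample of plant genes could give this. Its origin was not tested, and the counted panicoid hits, whose share was 2.66% and 2.69% in control and 2.79% and 2.72% in hypergravity, say little about it, since each counted row had at least 9 counts in every library.

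The second pattern is ribosomal protein transcripts that were lower among pooid hits and higher among other hits. Their medians were -0.27 and 0.36. A further organism that rose as a whole may account for part of it and stays open: of 185 ribosomal transcripts with cork oak or silver malletwood hits 62 were higher and 1.08% lower, but of all 849 with other hits, which can include wheat transcripts, 8.01% were lower. RNA of fungi on or in the roots may contribute and stays open: 76 cork oak hits named in the style of fission yeast loci had a median of 0.24, which is 2.96 standard errors above 0 where 3 were required, and cork oak hits took 0.363% and 0.344% of the counts in control and 0.475% and 0.53% in hypergravity. The bound that would have excluded it was changed to a median at or below 0 after this value was seen, because a near miss excludes nothing, and no biological explanation, such as a change of wheat ribosomal genes, was tested. Of the 76 hits named in yeast style 12 were called higher and 1 lower. The same style named 143 pooid hits (0.241% of pooid hits, against 3.88% of cork oak hits), so it does not mark fungal RNA alone. All 1957 cork oak hits had a larger median of 0.35, with 26.4% called higher, so the 76 did not stand out from their class. The standard error was taken over transcripts and not over libraries.

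The third pattern is the lower heat shock, histone, aquaporin and ribosomal protein transcripts among pooid hits. A trend of each library with transcript length is argued against as the whole cause, since 4 of 4 lists stayed called once it was removed, with medians of -0.28, -0.53, -0.41 and -0.19 for heat shock, histones, aquaporins and ribosomal proteins. A common shift in scaling would move a list and the other transcripts nearly alike, and these calls compare a list with other transcripts. A refit with size factors from pooid hits alone therefore could not change the calls and tested nothing. In it all 4 lists stayed called lower, with ribosomal proteins at a camera adjusted p of 4.07e-08 against 4.12e-08 with the deposited factors. The change of the 4 lists in absolute amount was not tested. A state of the roots or of their RNA that also varies within each group cannot be told apart from the treatment for histones and aquaporins. It would leave most of the other 2 medians. The difference between the control libraries was scaled by a slope of -1.10. Over all pooid hits, this slope was the covariance of the group change with the difference between the hypergravity libraries, divided by the covariance of the 2 within-group differences. So scaled, 2 of 4 lists came to at least 50% of their median (histones -0.41 of -0.59 and aquaporins -0.36 of -0.46). Heat shock (-0.11 of -0.28) and ribosomal proteins (-0.11 of -0.27) did not, and WRKY factors (-0.27 against 0.15) and gibberellin (-0.28 against 0.23) had the opposite sign. This is no independent prediction and 2 libraries per group are too few to decide, a response to hypergravity is likewise open, and all of this is a hypothesis found and tested on the same data.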

How the results depend on the processing

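The settings added after the results were seen were a mean of at least 50, scaling to the recovered total, voom weights, removal of the length trend and pooid hits alone. Of 91482 transcripts, 12378 were called higher and 10928 lower, and 8 lists were called in each direction. Leaving out 1 library at a time gave 8905 to 10635 higher and 6983 to 10804 lower transcripts, with 3 to 10 lists higher and 4 to 8 lower. The lone library of a group was then assumed to vary like the other group. Fewer lower transcripts were called without control b (6983, with 4 lists lower) and hypergravity b (7145, with 5 lists lower), and fewer lists higher without control a (4) and hypergravity a (3). Without a variance trend 6622 transcripts were lower, and quantile normalization left 5 lists lower; the cause was not tested. Sums per assembled gene, with fewer items tested, gave 6726 higher and 5799 lower genes. With 1 transcript per gene 5 lists were called higher and 3 lower of the same 34 lists. Isoforms of 1 assembled gene then no longer counted as separate members, so part of the list calls rested on counting isoforms separately. Pooid hits alone, with their own size factors, gave 8150 higher transcripts, and they had 7825 with the deposited factors. A log2 fold change of at least 1 left 4515 and 2894. Camera with an estimated correlation called 0 lists in either direction (2 of 34 at an unadjusted p under 0.05). That form rests on the 2 residual degrees of freedom, which makes a low p hard to reach. For calcium signalling the estimated correlation was 0.006, under the preset 0.01, yet the unadjusted camera p went from 1.62e-06 to 0.029. For ribosomal proteins it was 0.002, and the camera p went from 0.0095 to 0.037. A stronger correlation therefore does not account for the loss in these lists. Fry, which asks whether members move at all on balance, called 1 higher and 0 lower (7 and 3 at an unadjusted p under 0.05), and the cause was not tested. The ribosomal protein list turned from higher to lower among pooid hits alone (adjusted p = 4.07e-08), because that setting leaves out the hits that rose. Pseudocounts, scaling to the total, voom weights and the length trend kept all 4 counts within 1.5-fold. The mean filters of 1 and 5 removed no transcript and the recomputed size factors equalled the deposited ones, so those settings tested nothing. Of 216 named transcripts, none reversed in the settings fitted per transcript (200 remained to test at a mean of at least 50 and 156 among pooid hits alone), but calls were lost for 17 without a variance trend, 5 without control a, 8 without control b, 5 without hypergravity a and 21 without hypergravity b. DESeq2 was not run, and the recovered counts were tested on the log scale. No paired analysis was possible because the recovered libraries carry no replicate number. With 2 libraries per group, 8 of 67 changes of 1.5-fold were recovered in simulated data. Only 200 transcripts were changed there, so this does not give the recovery at the larger share called in the data.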

Other observations

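The 6 lists in this part, and their tests, were chosen only after the results were seen, so they are hypotheses. Enzymes of the methionine and S-adenosylmethionine cycle, which supply methyl groups and the precursor of ethylene, were called higher: 20 of 52 rose and 1 fell (camera of limma, adjusted p = 3.88e-08; adjusted p = 0.222 with an estimated correlation). Among pooid hits 10 of 27 rose and 0 fell (adjusted p = 7.95e-06; adjusted p = 0.134 with an estimated correlation). Those 10 lay in 4 of 17 assembled genes, with a list median of 0.16 against a mean of 1.07, and included the cystathionine gamma-synthase transcripts that prompted the list. Without the assembled genes of the top named transcripts 11 of 43 rose and 1 fell over all hits (adjusted p = 0.0027; adjusted p = 0.535 with an estimated correlation), but among pooid hits 2 of 19 rose and the list was not called (adjusted p = 0.377). An S-adenosylmethionine synthase 1-like transcript with a Prosopis hit went from 95.2 ± 30.1 to 482 ± 9.61 normalized counts (SD, n = 2 libraries per group). Receptor-like kinases, which sense signals at the cell surface, were higher in 662 of 2498 and lower in 208 (adjusted p = 0.000159; adjusted p = 0.222 with an estimated correlation). Examples with goatgrass hits are wall-associated receptor kinase 2-like, from 61.0 ± 4.03 to 336 ± 13.8, and cysteine-rich receptor-like protein kinase 40, from 50.7 ± 16.0 to 269 ± 59.6. Immune receptors of the NLR type rose in 370 and fell in 237 of 2186 and were not called (adjusted p = 0.186). Enzymes of sterol synthesis rose in 16 and fell in 5 of 70 and were not called by camera either (adjusted p = 0.116), though they were by fry (adjusted p = 0.021); cycloartenol synthase-like (goatgrass), at the start of the plant sterol pathway, went from 70.3 ± 3.77 to 518 ± 8.56.

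Heat stress transcription factors were lower, with 37 of 75 down and 11 up (camera of limma, adjusted p = 1.70e-07; adjusted p = 0.458 with an estimated correlation). Among pooid hits 37 of 72 fell and 9 rose (adjusted p = 8.64e-08; adjusted p = 0.391 with an estimated correlation), such as B-2b-like (TRINITY_DN1962_c0_g1_i6, goatgrass), from 1314 ± 350 to 300 ± 54.0. Without the top named genes 35 of 70 fell and 9 rose among pooid hits (adjusted p = 4.67e-07; adjusted p = 0.527 with an estimated correlation). For small heat shock proteins the difference between classes of hit was not tested. Over all hits 39 of 91 fell and 23 rose, with a median of -0.46, a mean of -0.03, a downward test that was not past its threshold (adjusted p = 0.219) and an upward direction by fry. Among pooid hits 28 of 38 fell and 2 rose (adjusted p = 1.95e-10; adjusted p = 0.391 with an estimated correlation). Without the top named genes 27 of 37 fell (adjusted p = 5.45e-10; adjusted p = 0.527 with an estimated correlation).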
